A study of Homo sapiens with 20 samples.

How the data were processed

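Total RNA from 20 KYSE esophageal cancer cell lines was measured with 1 array per line. Per the labels, the arrays were commercial CodeLink Human 20K oligonucleotide arrays, the images were read with CodeLink Expression Analysis version 2.3, and each array was normalized globally. Per the file headers, the scanner files are in spot-finding format version 5.5, were made with automatic segmentation, and give the mean intensity of each spot, the median intensity of its local background and a quality flag for empty or poor spots. The table of values deposited by the authors holds intensity on a linear scale. Checked against the scanner files, each value equals the spot mean minus the background median, divided by 1 constant per array (largest difference 7.6e-08). The column medians of that table were 0.969 to 0.9798, and 2622 values were 0 or below. Of its 20470 entries 20313 were matched to spots, 156 were missing on all arrays and 513 on some.

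The main values were computed from the scanner files. Spots with the poor flag were left out (0.6535% of spots). Background was corrected by the normexp method with an offset of 50, arrays were quantile normalized over the human probe spots and values were taken to log2, with limma 3.58.1 in R 4.3.3, with files read by the package data.table, version 1.17.8. Spots of the same probe were averaged. For 124 probes spotted more than once, the pooled SD within an array was 0.48 and the median SD 0.26 on the log2 scale. A probe was above background where its mean exceeded the local background median plus 1.5 background SDs, and a gene passed detection when this held on at least 5 of the 20 arrays. Probes were named by the platform's annotation and checked against RefSeq gene names of the assembly GRCh38.p14, which was also used for the order of genes. Of 20060 human probe spots 16034 had 1 symbol, 86 had several and 3940 had none, which were left out. The genome build behind the probe design is not stated. The probe with the highest mean signal stood for a gene with several probes (2214 of 13454 genes), and 12874 genes passed detection. Genes whose level depends on sex chromosomes or on common inherited deletions, and genes of tissue type, were left out (57 probes). Of these genes 1328 had a missing value, 1037 of them on 1 array. Missing values were set to the gene's mean for correlations, scores, the ranking by SD and the count of SDs above 1. They were left missing in limma and in the SDs printed for single genes.

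The design, 36 gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The lists covered 14 programmes (NRF2 targets, basal squamous, cornified, mesenchymal, epithelial, proliferation, interferon, hypoxia, cholesterol, ATF4, p53, cancer-testis, metallothionein and ribosomal genes), 8 chromosome regions, 8 groups of drug genes and 6 groups of markers of other cell types. Genes were named by these rules: the 25 with the largest SD, the top gene of each line with a gap of at least 3 (8-fold) to the second line, members of the drug lists and planned relations, per anchored fit up to 6 genes in each direction with the largest moderated t, and for other lists the members with the largest SD. CES1 and CBR3 in the anchored fit were named as drug genes. The members passing over a list alone, those named for a high level among markers of other cell types, and PCNA, CDC6, UCK2 and FANCL among the probes split by batch, were chosen after their values were seen.

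Co-expression of a list was the mean pairwise Pearson r of its passing members over the 20 lines, tested one-sided against 10000 random gene sets matched in 20 bins of mean signal. A list score was the mean z score of its members. Relations were tested two-sided with 100000 permutations for r and rho, with Benjamini-Hochberg adjustment within each family (35 lists, 20 score relations, 28 drug gene relations), and r was given again without the 2 lines farthest from the median and within each scan batch. No pooled r was given where the largest gap in either measure, multiplied by 3, exceeded the whole range of that measure, with at least 3 lines on each side. Anchored fits used limma with a trend on the standardised score, left out the members of the list, and were repeated on 100 permutations of the score over genes without missing values. Neighbouring genes were tested against 1000 shuffles of the gene order. An adjusted p below 0.05 counted as a call. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

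The methods were tested on simulated data of the same size. There each gene was independent normal noise apart from the planted effects, with no scan batches. The rates below therefore do not cover the batch effects and the correlation between genes in the real data. Permutations of the real scores called up to 94 genes for the cornified score and 61 for the interferon score (median 0 for each). All 10 simulated lists with a shared factor were recovered and 0 of 20 without one were called. Of 500 unrelated pairs 4.4% had p below 0.05, as did 96.5% of 200 pairs with a true r of 0.7. Gene order without blocks gave p of 0.4279 and with blocks of 10 genes 0.005. The anchored fit recovered 57 of 100 genes with a slope of 1 gene SD, 100 of 100 with 2, and called 11 of 12674 unchanged genes.

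Scan batches were read from the scanner headers, where scan day and slide series coincide. The other settings fixed in advance were raw signal without background correction, median scaling, the authors' values, no filter, a filter for all 20 arrays, the mean of all probes, Spearman correlation, removal of the first principal component, scores from a principal component, a gap of 2, a covariate for the share of probes above background, robust limma, scan batch as a block in the anchored fits, and leaving out KYSE890. Removal of scan batch means, a filter on negative control probes, masking of values missing in the authors' table, keeping poor spots, measured values only, and a scan of chromosome windows of 11 genes with 200 shuffles were added after the data were seen. With measured values only, lines without a value were left out of SDs, gaps and relations, members without a value were left out of scores, and genes with a missing value were left out of the other correlations. Drug response values were not among the data.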

Results

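Gene expression was measured in 20 KYSE lines, a series of cell lines grown from human esophageal cancers. Each line had 1 array, a CodeLink Human 20K glass array with 1 short oligonucleotide probe per spot. The study looked for genes tied to the response of the lines to anticancer drugs. The drug response values themselves were not analysed here, because neither the labels nor the files hold them. All 20 lines fall into 1 group, with no treated or untreated partner and no replicate array, so every SD below is a spread between lines that also holds array error. Each SD is over the arrays whose spot was not scored poor, 20 unless n is given. Signals are on a log2 scale, with a floor near 6.

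Each array read 21132 spots, of which 20060 carried probes for human genes. Between 85.3% (KYSE150) and 93.7% (KYSE450) of the human probe spots lay above their local background, and the median signal was 2.87 to 4.52 times the median background. Of 252 negative control spots, 2.38% to 15.1% passed the same background limit. The number of arrays, 1 per line, limits the precision of every value. The scanner headers placed the arrays in 3 scan batches of 6, 8 and 6 lines, numbered here by rising background. Batch 1 held KYSE170, KYSE200, KYSE350, KYSE450, KYSE520 and KYSE590, batch 2 held KYSE150, KYSE180, KYSE220, KYSE850, KYSE890, KYSE1170, KYSE1190 and KYSE2270, and batch 3 held KYSE30, KYSE140, KYSE410, KYSE510, KYSE770 and KYSE1250. The median gene had 23.8% of its variance between scan batches. With no batch effect the expected mean share, which is not a median, is 10.5%. The first principal component held 15.3% of the variance, with 63.9% of it between batches. Components 2 and 3 held 12.96% and 8.58%, with 90.7% and 25.5% between batches.

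The first question was which genes differed most between the lines. MAGEA4, a cancer-testis antigen that most normal adult tissues do not express, was on at 12.20 to 14.65 in 10 lines and near the floor at 6.11 to 6.88 in the other 10. KRT19, a keratin of simple epithelia, reached at least 12.67 in 10 lines and lay between 5.96 and 8.46 in the others. KRT5, the keratin of basal squamous cells, ran from 5.95 in KYSE30 to 14.97 in KYSE850 (mean 11.11 ± 3.40, SD, n = 20). SPP1, the secreted phosphoprotein osteopontin, ran from 5.79 in KYSE450 to 14.76 in KYSE850 (9.84 ± 3.25). VIM, the intermediate filament protein vimentin of mesenchymal cells, ran from 5.78 in KYSE180 to 13.86 in KYSE1190 (8.56 ± 2.74).

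Among the 25 genes with the largest SD were the aldo-keto reductases AKR1B10 (11.81 ± 2.97, n = 19) and AKR1C3 (12.23 ± 3.02, n = 17), the glutathione transferase MGST1 (11.15 ± 3.92, n = 11), the alcohol dehydrogenase ADH7 (8.69 ± 2.78), the aldehyde dehydrogenase ALDH1A1 (8.84 ± 2.75) and the carboxylesterase CES1 (9.24 ± 2.75, n = 19). The 25 were ranked with poor spots set to the gene's mean, which lowers the SD. Over measured arrays alone MGST1 ranked 2 and AKR1C1 (SD 2.76, n = 16) took the place of TENM2. The poor spots of AKR1C3 were in KYSE200, KYSE850 and KYSE1250, and that of AKR1B10 was in KYSE890. These lines had high NRF2 target scores (0.71 to 0.98), so the arrays left out were not a random set. Secreted proteins were PI3, an elastase inhibitor (9.23 ± 2.97), CXCL14, a chemokine (8.19 ± 2.92), and PLAU, the urokinase protease (11.05 ± 2.78). The remaining ones with a spread inside the scan batches were GTSF1, a germ cell factor (8.28 ± 3.46), UCHL1, a ubiquitin hydrolase of neurons (9.62 ± 3.42), S100P, a calcium-binding protein (9.98 ± 2.79), SNRPN, an imprinted gene for a splicing protein (9.10 ± 2.81, n = 19), and TENM2, a teneurin (8.23 ± 2.68). In all, 742 of the 12874 genes that passed detection had an SD above 1, and the median SD was 0.38. These variable genes numbered 749 over measured arrays alone, 1619 with the authors' values and 333 with the filter for all 20 arrays.

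The other 6 of the 25 genes were split by scan batch. HSPA8, a heat shock protein of the cytosol, had an SD of 4.53 over all lines and 0.17 within batches. EIF4G1, a scaffold of translation initiation, had 3.54 and 0.22, MRPS24, a mitochondrial ribosomal protein, had 3.46 and 0.15 (n = 19), and ADI1, an enzyme of methionine salvage, had 3.28 and 0.28 (n = 19). DDX50, an RNA helicase, had 2.87 and 0.38, and BABAM1, a member of a BRCA1 complex, had 2.78 and 0.37. Such probes read near the floor on every array of some batches and well above it on every array of the others. A limit of 2 on the log2 scale, chosen after the data were seen, found 49 such probes. Of these, 9 were lower in batch 1, 16 in batch 2 and 22 in batch 3, and 2 were higher in batch 2. PCNA, a clamp of DNA replication, CDC6, a factor of replication origins, UCK2, a kinase that can activate fluorouracil, and FANCL, a ligase of crosslink repair, were among them. Their within-batch SDs were 0.25, 0.35, 0.33 and 0.29, against 2.50, 2.27, 1.89 and 2.24 over all lines.

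The second question was which genes stood out in a single line. KYSE1190 had FSCN2, an actin-bundling protein of photoreceptors, 88.2 times above the second line, a gap of 6.46. KYSE350 had DPP6, a subunit of potassium channels, 33.4 times above the second line (gap 5.06). In KYSE30 the heme-degrading enzyme HMOX1 lay 25.7 times above the second line (gap 4.69). LUM, a proteoglycan of connective tissue, was 20.4 times above the second line in KYSE410 (gap 4.35). That line also had ERBB2, a growth factor receptor, with its chromosome neighbour PGAP3, at gaps of 3.19 and 3.50. KYSE200 had the chemokine CCL24 (gap 3.60), KYSE510 the glycine-degrading enzyme GLDC (3.54), and KYSE2270 the chemokine CXCL6 (3.28). The top genes of KYSE890, KYSE150 and KYSE140 were KRABD1 (3.63), CPED1 (3.38) and BEX4 (3.37). Among genes above background on at least 1 array, gaps of at least 3 were found for 28, 6 of them in KYSE410 and 4 in KYSE350, and 10 lines had none. GLDC was above background on 2 arrays and CPED1 on 3. The count was 79 with the authors' values, 55 with poor spots kept, 18 with no background correction, 13 with scan batch means removed and 11 with the filter for all 20 arrays. Where the second line lay near the floor, the fold is a lower bound. No test was run, because each line had 1 array.

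The third question was whether the genes of a known programme varied together between lines. The largest mean correlations among cellular programmes belonged to targets of NRF2, the transcription factor of the oxidative stress response, and to epithelial genes. The 24 measured NRF2 targets had a mean pairwise r of 0.417 over the 20 lines, against 0.0384 at the 95th percentile of random gene sets of like signal. The 22 epithelial genes had 0.266. Among chromosome regions, the 9 genes of 18p11 had 0.617 and the 7 genes of 7p11 had 0.496. Of 35 lists tested, 17 had an adjusted p below 0.05 (one-sided test against 10000 random sets). The adjusted p was 0.000318 for the NRF2, epithelial, 18p11 and 7p11 lists, from 0.0001, the smallest p these sets can give.

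The genes of squamous differentiation also varied together. The 16 basal squamous markers had a mean r of 0.161 (adjusted p = 0.000808), with KRT14, a basal keratin (9.35 ± 2.53), S100A2, a calcium-binding protein (13.43 ± 1.40, n = 19), and DSC3, a desmosomal cadherin (10.07 ± 1.14), next to KRT5 in spread. The 30 cornified differentiation genes had 0.145 (adjusted p = 0.000318), led by PI3, SLPI, a protease inhibitor (9.89 ± 2.37), and KRT13, a keratin of the esophageal lining (11.62 ± 2.33). In the epithelial list RAB25, a GTPase of membrane traffic (11.12 ± 2.12), KRT8, a simple keratin (12.19 ± 2.13, n = 19), and CLDN1, a tight junction protein (8.06 ± 1.62, SD 0.64 within batches), followed KRT19. KYSE1190 had the lowest epithelial score of all lines, -1.84, and the lowest KRT19 and KRT8. The 22 mesenchymal genes did not pass (mean r 0.0466, adjusted p = 0.0998) but did with scan batch means removed (0.0508, adjusted p = 0.0266). Of these genes 12 had an SD above 1, among them TGFBI, a matrix protein (9.94 ± 2.17), and CCN2, a matricellular growth factor (9.96 ± 2.0, n = 18).

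Lists of stress and growth programmes passed too. The 21 targets of ATF4, the factor of amino acid shortage, had a mean r of 0.182 (adjusted p = 0.000318). Their score was highest in KYSE30, at 1.39 against 0.566 in the next line, where the asparagine synthetase ASNS reached 13.74 (11.42 ± 0.76 over the lines, n = 19). PHGDH, the first enzyme of serine synthesis (9.48 ± 0.94), and TRIB3, a pseudokinase (9.52 ± 0.86), had the largest SDs. The 28 interferon-induced genes had 0.135 (adjusted p = 0.000583), led by BST2, a tether of budding virus (8.76 ± 2.56), IFI27 (9.02 ± 1.81) and IFI44 (8.79 ± 1.55). The 38 proliferation genes had 0.132 (adjusted p = 0.000318), with MCM7, a replication helicase subunit (12.60 ± 0.94, n = 19), and KIF20A, a mitotic kinesin (9.15 ± 0.78). The 2 members with an SD above 1, PCNA and CDC6, had probes split by scan batch and stayed in the list and its score. The 22 hypoxia and glycolysis genes had 0.110 (adjusted p = 0.001), with BNIP3, a mitophagy receptor (11.32 ± 1.33), the stress protein DDIT4 (10.12 ± 1.32) and NDRG1 (10.05 ± 1.21). The list lost its call with median scaling and with the authors' values. Its score was highest in KYSE510, at 1.09. The 14 cancer-testis genes had 0.143 (adjusted p = 0.0117), a call lost with the filter for all 20 arrays, with MAGEA12 (8.67 ± 2.25), PRAME (8.60 ± 1.69) and MAGEA1 (7.62 ± 1.66) after MAGEA4. KYSE170 had the highest scores for interferon (0.833) and for cancer-testis genes (0.850).

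Other programmes did not pass. The 17 genes of cholesterol synthesis had a mean r of 0.0673 (adjusted p = 0.0507, and 0.0266 with scan batch means removed), with the sterol enzymes DHCR7 (11.16 ± 1.51) and MSMO1 (8.75 ± 1.09). The 23 p53 targets had 0.0198 (adjusted p = 0.230), with the cytokine GDF15 (10.78 ± 2.22, n = 19), TP53I3 (8.29 ± 1.12) and the cell cycle inhibitor CDKN1A (11.52 ± 1.09). The 7 metallothioneins, which bind metal ions, had 0.000461 (adjusted p = 0.50), with MT1E (9.31 ± 1.07) and MT1F (7.32 ± 0.94). The 15 ribosomal proteins had 0.00448 (adjusted p = 0.529), with RPS23 (9.40 ± 0.56) and RPL11 (10.82 ± 0.50). With scan batch means removed 21 lists passed, 16 of them shared with the 17. The 5 gained were the cholesterol, mesenchymal, reductive activation, apoptosis and endothelial lists. The list of topoisomerase drugs was lost, with an adjusted p of 0.265.

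**Figure D1:**
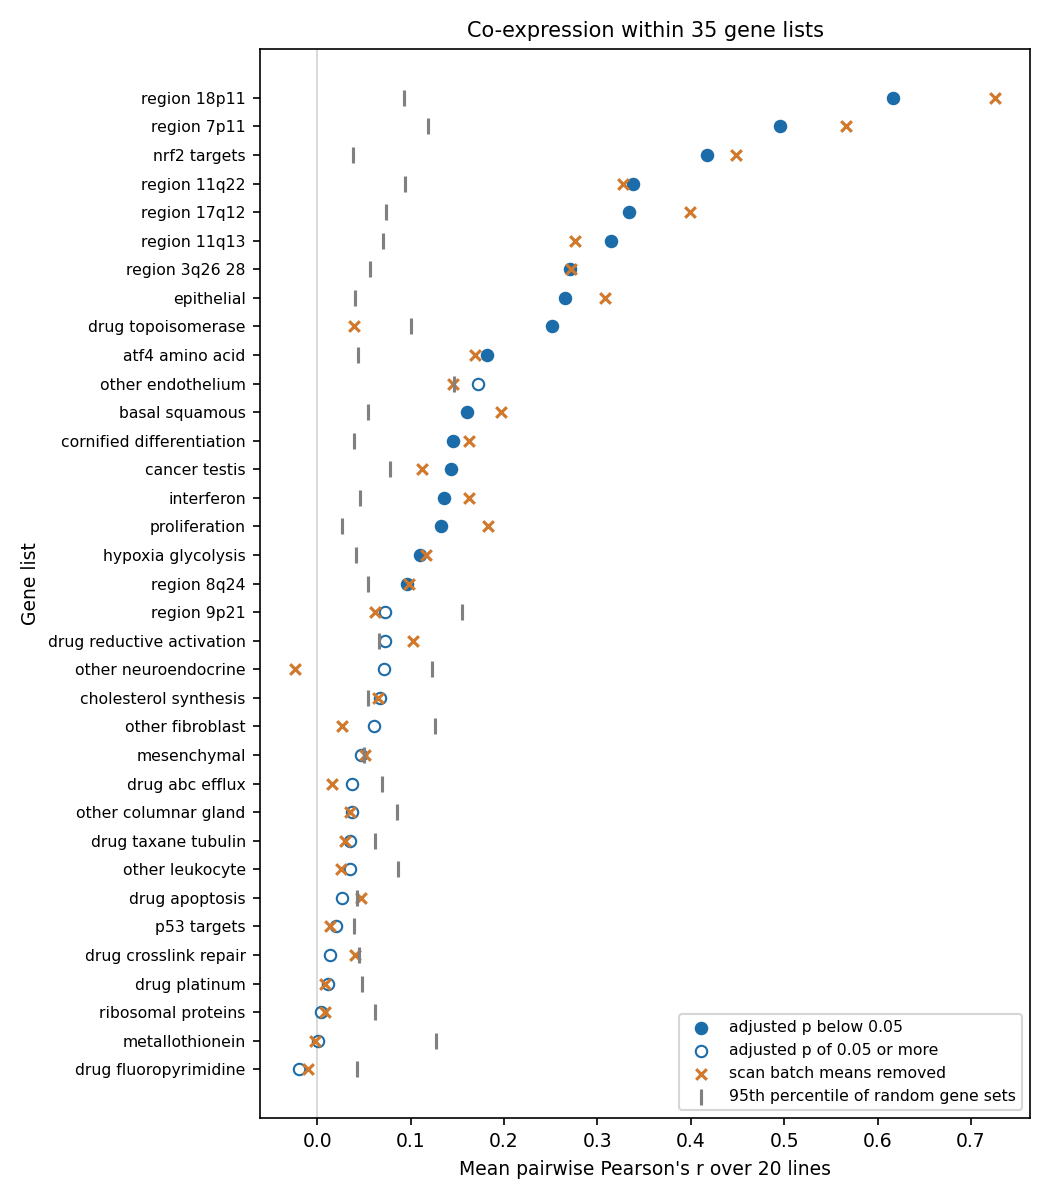
Mean pairwise Pearson's r over the 20 lines for each of 35 gene lists, with the 95th percentile of random gene sets (grey ticks) and the value after scan batch means were removed (crosses). Filled points mark the 17 lists with an adjusted p below 0.05, from 0.617 for 18p11 to 0.0961 for 8q24.

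The fourth question was which other genes followed the NRF2 target score. SPP1 rose with it most steeply among the named genes, by 3.0 ± 0.277 on the log2 scale per SD of the score (slope ± SE, n = 20, adjusted p = 7.2e-06, limma). The fatty acid hydroxylases CYP4F11 (0.93 ± 0.101, adjusted p = 6.23e-05) and CYP4F2 (1.30 ± 0.167, 0.000324) rose as well, as did the glutathione transferase GSTM4 (1.12 ± 0.136, 0.000175). TFF3, a mucosal peptide (0.94 ± 0.106, 0.000121), and ADH7 (2.41 ± 0.310, 0.000324) were the other 2 of the 6 named genes that rose. The drug-metabolising enzymes CES1 (2.39 ± 0.333, adjusted p = 0.000817) and CBR3, a carbonyl reductase (1.03 ± 0.190, 0.0121), also rose with the score. In all, 45 of 12850 genes outside the list passed, 41 up and 4 down. The 4 that fell were URGCP (-0.35 ± 0.066, adjusted p = 0.0136), MIOS, a part of a nutrient-sensing complex (-0.43 ± 0.0899, 0.0344), MB21D2 (-0.31 ± 0.0665, 0.0374) and the splicing factor SRSF9 (-0.20 ± 0.0423, 0.0374).

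SPP1 and the score correlated with r of 0.923 and rho of 0.887, each with a permutation p of 1e-05, the smallest possible. Without KYSE850 and KYSE1190, the lines farthest from the median score, r was 0.912. Within batches 1, 2 and 3 r was 0.884, 0.95 and 0.903. SPP1 was named for its fit to this same score, so these values are not an independent test. ADH7 levels fell into separate clusters, so no pooled r is given for it. With scan batch as a block in limma 44 genes passed, 33 of them shared with the 45, and SPP1 kept a slope of 3.03 (adjusted p = 0.000189). SRSF9 lost its call with the block (adjusted p = 0.0504) and its slope turned to 0.04 with the authors' values. In the 100 permutations of the score, run on the 11529 genes without missing values, at most 1 gene passed, against 36 for the real score.

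Among the 8 lists of drug genes, 5 members passed when adjusted over the list alone, against 2 over all genes tested. CES1 (fluoropyrimidine list) and CBR3 (reductive activation list) were called both ways. The other 3 were GSTM3, a glutathione transferase of the platinum list (1.34 ± 0.362, adjusted p = 0.0290 over the list), and 2 genes of the taxane list, MAP2, a microtubule-associated protein (0.46 ± 0.107, 0.00610), and TUBB3, a beta tubulin (-0.46 ± 0.138, 0.0239). No member of the efflux, topoisomerase, apoptosis and crosslink repair lists passed either way. The efflux gene ABCC2 was left out of this fit as a member of the NRF2 list, and ABCC1 and ABCC3 were not measured. Among the other lists, 3 of the 7 metallothioneins passed over the list alone, MT1L up and MT1E and MT1X down, and none over all genes. So did CDH3 and DDIT4, which fell, and COL3A1 and RPS23, which rose, 1 in each of their lists. With scan batch as a block CDH3, DDIT4, COL3A1 and MT1X lost these calls, and RPS23 was called over all genes (adjusted p = 0.0166). NRF2 target scores were highest in KYSE850 (0.978), KYSE1190 (0.952) and KYSE890 (0.864) and lowest in KYSE140 (-1.01), KYSE150 (-0.979) and KYSE450 (-0.676).

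**Figure D2:**
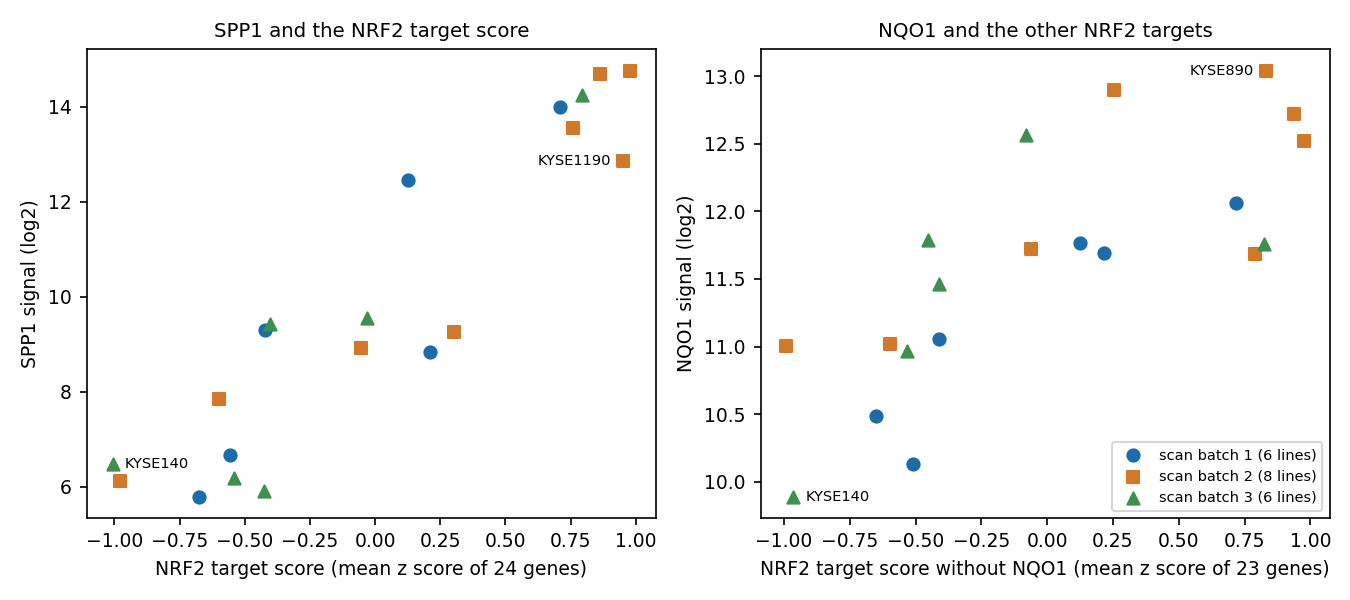
SPP1 signal against the NRF2 target score, and NQO1 signal against the score without NQO1, with 1 point per cell line marked by scan batch. SPP1 rose from 5.79 to 14.76 and NQO1 lay between 9.89 in KYSE140 and 13.04 in KYSE890.

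The remaining scores drew few genes with them. SMC2, a condensin subunit that packs mitotic chromosomes, rose with the proliferation score (slope 0.40 ± 0.0604, adjusted p = 0.0234, r 0.859, rho 0.808, without KYSE30 and KYSE140 0.774). The permutation p of r was 1e-05, the smallest possible, that of rho was 4e-05, and r within batches 1, 2 and 3 was 0.477, 0.812 and 0.958. SMC2 was named for its fit to this same score, so these values are not an independent test. It was the only gene called by limma for that score, with 1485 at an unadjusted p below 0.05. That count depended on the scaling of the arrays, with 831 genes called from the authors' values and 476 with median scaling. Over genes without missing values 2 were called, and 2 of 100 permutations of the score called as many. With scan batch as a block 14 genes passed, 7 up and 7 down. Over genes without missing values the block gave 15, and 0 of 100 permutations within batches called as many (at most 5). Adjusted over the list alone, 4 of 18 fluoropyrimidine genes passed with 0 over all genes: RRM1, a ribonucleotide reductase subunit (0.34 ± 0.106), DUT, the dUTPase (0.30 ± 0.0931), and TDG, a DNA glycosylase (0.37 ± 0.0829), rose, and DPYD, the enzyme that breaks down fluorouracil, fell (-0.68 ± 0.229). With the block DUT and DPYD lost these calls, and UMPS and UPP1 passed beside RRM1 and TDG. Other lists also had such calls with this score and 0 over all genes: PLK2, PLK3 and SESN1 of the p53 list, ATAD2 and RAD21 of 8q24, XRCC6, CYB5R3 and TBL1XR1. With the block RAD21 and CYB5R3 lost these calls, and ATAD2 was called over all genes (adjusted p = 0.0414). The block also added GDF15 and TNFRSF10B of the p53 list, SESN2, TRIB3, GJB5, LAMB3, S100A2, ABCA2 and CCN1 over their lists. With the mesenchymal score 4 of 7 genes of 7p11 rose when adjusted over the list alone, among them VOPP1 (0.83 ± 0.147) and EGFR (0.85 ± 0.280), with 0 over all genes. The lines with the highest 7p11 scores, KYSE30, KYSE520 and KYSE590, also had the highest mesenchymal scores. These fits were not repeated without them. ITGA6, MT1X and MED1 passed over their lists with the mesenchymal score, and TRIB1 with the interferon score. With the block ITGA6 lost its call, SUMF2, SOD1 and MX1 gained one with the mesenchymal score, and CD79A and ZMAT3 gained one with the cornified score. In limma 0 genes were called for the mesenchymal, cornified and interferon scores, with 978, 582 and 491 at an unadjusted p below 0.05.

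The fifth question, from the purpose of the study, was how genes of drug handling differ between the lines. In the fluoropyrimidine list, CDA, which deaminates cytidine analogues (7.25 ± 1.28), and DPYD (8.30 ± 1.24) had their highest levels in KYSE890, at 9.69 and 10.89. UPP1, a phosphorylase that can activate fluorouracil (10.90 ± 1.19), peaked at 13.28 in KYSE30. TYMS, the thymidylate synthase that fluorouracil blocks, ran from 9.80 in KYSE890 to 12.44 in KYSE350 (11.07 ± 0.73, n = 19). TYMP, another activating phosphorylase, had 7.02 ± 0.76, the ribonucleotide reductase subunits RRM1 and RRM2 had 10.24 ± 0.57 and 8.86 ± 0.48 (n = 19 for RRM2), and the kinase TK1 had 13.43 ± 0.44. The 21 measured genes did not vary together (mean r -0.0190, adjusted p = 0.892), and 5 had an SD above 1.

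In the platinum list, GSTP1, a glutathione transferase, lay at 10.26 in KYSE410 and at 13.41 to 14.88 in the other 19 lines (14.01 ± 0.99). GSTM3 ran from 8.06 to 14.60 (11.78 ± 2.11). The repair genes ERCC1 (9.15 ± 0.42) and ERCC2 (8.26 ± 0.24) and the copper transporters ATP7A (7.78 ± 0.69) and ATP7B (7.0 ± 0.38) varied less. MGMT, which removes alkyl groups from guanine, ran from 6.15 in KYSE1170 to 12.18 in KYSE200 (9.26 ± 2.46) and led the crosslink repair list, followed by FANCL and then RAD50, a strand break repair protein (10.22 ± 0.73). These lists did not vary together (platinum mean r 0.0116, adjusted p = 0.370, crosslink repair 0.0137, adjusted p = 0.311).

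Among 14 efflux genes, the major vault protein MVP (8.57 ± 0.79) and ABCG2 (9.90 ± 0.59) were above background in every line. ABCC2 (8.37 ± 1.84) ran from 6.03 in KYSE410, at the floor, to 11.68 in KYSE1250, and ABCB1, the P-glycoprotein gene, lay near the floor (6.27 ± 0.19, above background on 11 arrays). Their mean r was 0.0374 (adjusted p = 0.221). The topoisomerase list passed (mean r 0.252, adjusted p = 0.0021), but with scan batch means removed its mean r was 0.0392 (adjusted p = 0.265). It held the drug targets TOP1 (8.30 ± 0.76, SD 0.30 within batches), TOP2A (10.38 ± 0.59) and TOP2B (7.54 ± 0.64). In the taxane list the microtubule-binding protein MAPT (8.42 ± 0.91, n = 19) and the tubulins TUBB3 (7.36 ± 0.77) and TUBB6 (13.21 ± 0.74, n = 19, lowest in KYSE890 at 10.60) had the largest spreads, and STMN1, which takes microtubules apart, had 13.93 ± 0.28 (mean r 0.0357, adjusted p = 0.213).

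In the reductive activation list CBR3 (9.97 ± 1.34), POR, the reductase of cytochromes P450 (7.84 ± 0.87), and CBR1 (11.91 ± 0.84, n = 19) had large spreads after AKR1C3 (mean r of the list 0.0727, adjusted p = 0.0663). With scan batch means removed that list passed (0.102, adjusted p = 0.0144). In the apoptosis list BIK, a BH3-only protein (9.56 ± 0.98), and BIRC2, an inhibitor of apoptosis (9.02 ± 0.97), had the largest spreads (mean r 0.0269, adjusted p = 0.201, and with scan batch means removed 0.0465, adjusted p = 0.0277). The anti-apoptotic BCL2L1 was even over the lines (9.93 ± 0.21) and BCL2 was near the floor (6.24 ± 0.12, above background on 11 arrays).

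Of 35 planned relations of these genes, 28 were tested and 6 passed. Poor spots were set to the gene's mean in them, for TYMS and EGFR in KYSE590 and for CBR1 in KYSE200. TYMS followed its chromosome neighbours: its signal and the score of 8 other 18p11 genes had an r of 0.811 (permutation p = 3e-05, adjusted p = 0.00084) and a rho of 0.710 (permutation p = 0.0008). Without KYSE350 and KYSE520 r was 0.720, and within batches 1, 2 and 3 it was 0.922, 0.813 and 0.876. With measured values only r was 0.841 (n = 19, adjusted p = 0.00084). TYMS did not follow the proliferation score (r -0.082, permutation p = 0.733, adjusted p = 0.820, rho -0.0857, permutation p = 0.720, without the same lines 0.126, within batches -0.259, 0.537 and -0.00706). EGFR followed the 6 other genes of 7p11, with r of 0.725 (permutation p = 0.00039, adjusted p = 0.00273) and rho of 0.708 (permutation p = 0.00056). Within batches that r was 0.645, 0.738 and 0.836, and without KYSE30 and KYSE520 it was 0.453 (permutation p = 0.0602), so the call depends on those lines. With measured values only r was 0.783 (n = 19, adjusted p = 0.00112).

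NQO1, a quinone reductase that activates some bioreductive drugs, followed the NRF2 score with r of 0.772 (permutation p = 0.00014, adjusted p = 0.00196) and rho of 0.797 (permutation p = 7e-05). Without KYSE140 and KYSE170 r was 0.738, and within batches it was 0.917, 0.794 and 0.618. CBR1, a carbonyl reductase that acts on anthracyclines, followed the same score with r of 0.752 (permutation p = 0.00022, adjusted p = 0.00205) and rho of 0.717 (permutation p = 0.00064). Its r was 0.745 without KYSE850 and KYSE350, and 0.307, 0.864 and 0.817 within batches. With measured values only it was 0.783 (n = 19, adjusted p = 0.00112). TK1, a kinase of thymidine salvage, followed the proliferation score with r of 0.694 (permutation p = 0.00063, adjusted p = 0.00353) and rho of 0.691 (permutation p = 0.00092), 0.623 without KYSE770 and KYSE140, and 0.515, 0.437 and 0.818 within batches. RRM1 followed it with r of 0.598 (permutation p = 0.0054, adjusted p = 0.0252), rho of 0.562 (permutation p = 0.0112) and 0.970, 0.633 and 0.693 within batches. Without KYSE1190 and KYSE30 its r was 0.463 (permutation p = 0.0545), so the call depends on those lines.

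The other 22 tested relations did not pass. With measured values only 8 relations passed: the 6 above, STMN1 and proliferation (r 0.539, adjusted p = 0.0478) and EGFR and the mesenchymal score (r 0.571, adjusted p = 0.0478, n = 19). For the latter, the values with KYSE590 set to the mean were r 0.519 (permutation p = 0.0192, adjusted p = 0.0643) and rho 0.347 (permutation p = 0.135), with 0.122 without KYSE30 and KYSE520 and 0.696, 0.206 and 0.577 within batches. The nearest were the microtubule regulator STMN1 with proliferation (r 0.544, permutation p = 0.0126, adjusted p = 0.0506, rho 0.502, permutation p = 0.0247, without KYSE1190 and KYSE2270 0.549, within batches -0.186, 0.524 and 0.752) and TOP2A with proliferation (r 0.518, permutation p = 0.0207, adjusted p = 0.0643, rho 0.538, permutation p = 0.0162, without KYSE510 and KYSE140 0.466, within batches 0.277, 0.293 and 0.515). ERBB2 and its 17q12 neighbours had r of 0.798 (permutation p = 0.0278, adjusted p = 0.0777) but rho of 0.129 (permutation p = 0.586), with 0.284, -0.268 and 0.976 within batches. Without KYSE410 and KYSE890 r was 0.0333, so the value rests on those lines. GSTP1 and the NRF2 score had r of 0.424 (permutation p = 0.0366, adjusted p = 0.0880), rho of 0.520 (permutation p = 0.0201) and 0.119, 0.450 and 0.428 within batches. Without KYSE410 and KYSE220 r was 0.729 (permutation p = 0.00068). BIRC2 and MTAP levels fell into clusters of 16 and 4 lines and of 3 and 17 lines, so no pooled r is given. In the larger clusters r with the neighbours was 0.244 (permutation p = 0.364) and 0.223 (permutation p = 0.391). Among the relations not tested were those of CCND1, ABCC1, ABCC3 and MT2A, because these genes were not measured.

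Of 20 planned relations between list scores, 0 passed with permutation tests, and 1 had an unadjusted p of r below 0.05. With scores from a principal component 5 passed: epithelial with mesenchymal, basal squamous with epithelial, NRF2 with metallothionein, and cholesterol and p53 each with proliferation. The relation of cholesterol and proliferation also passed with median scaling and with the filter for all 20 arrays, where basal squamous with mesenchymal passed too. The 1 relation set cholesterol synthesis against proliferation, with r of 0.571 (permutation p = 0.00875, adjusted p = 0.175) and rho of 0.594 (permutation p = 0.00673). Without the 2 farthest lines r was 0.493, and within batches it was 0.548, -0.0295 and 0.718. The epithelial and mesenchymal scores had r of -0.00135 (permutation p = 0.995, adjusted p = 0.995), rho of 0.152 (permutation p = 0.520), 0.136 without KYSE1190 and KYSE350, and 0.383, -0.240 and 0.398 within batches.

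The sixth question was whether expression followed chromosome position. In KYSE410 the 12 genes of 17q12 lay 1.90 ± 1.68 above the line median on average (SD over genes), and 9 of them were highest there. ERBB2 was 4.61 above the median and its neighbours PGAP3, MIEN1 and STARD3, a cholesterol-binding protein, were 3.92, 3.30 and 3.23 above it. In KYSE2270 the 10 genes of 11q22 lay 2.04 ± 2.23 above, with the matrix proteases MMP7 and MMP1 at 7.33 and 3.47, the growth regulator YAP1 at 2.67 and BIRC2 at 2.43. The same region had means of 1.14 in KYSE170 and 1.05 in KYSE410. KYSE30 had 7p11 at 1.52 ± 1.25, with EGFR at 3.89, and KYSE520 had it at 1.16. KYSE520 also had the highest 18p11 mean, 1.15 ± 0.384, followed by KYSE510 at 1.06 and KYSE350 at 0.66.

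The 12 genes of 11q13 had means of 0.97, 0.95 and 0.88 in KYSE140, KYSE1250 and KYSE1170, with ANO1, a chloride channel (9.22 ± 1.40), FADD, a death receptor adaptor (9.81 ± 1.09), and TPCN2, a lysosomal ion channel (9.02 ± 1.03). The 15 genes of 8q24 had 0.84 in KYSE510, where MYC reached 14.67 (12.60 ± 0.89), and 0.79 in KYSE590, and TATDN1 had the largest spread (10.82 ± 1.80). The 15 genes of 3q26-28 had their highest scores, as mean z, in KYSE1170 (1.10), KYSE180 (0.856) and KYSE140 (0.783), and 7 of them were highest in KYSE1170. Their largest spreads included SOX2, a stem cell and squamous transcription factor (11.05 ± 2.16), and TFRC, the transferrin receptor (9.92 ± 0.86). That list also held EIF4G1, which was near the floor in batch 2, the batch of KYSE1170 and KYSE180. In 9p21 the methylthioadenosine phosphorylase MTAP was near the floor in KYSE890, KYSE1190 and KYSE170, at 5.89, 6.01 and 6.24, and at least 9.08 in the other 17 lines. CDKN2A, the inhibitor of cyclin-dependent kinases next to it, had 7.41 ± 1.15. KYSE200 had the highest 9p21 mean, 0.83 ± 1.54 (SD over genes), but only 1 of the 6 genes lay more than 1 above its median there. The adjusted p of co-expression was 0.000318 for 11q13, 3q26-28, 17q12 and 11q22 (mean r 0.315, 0.271, 0.334 and 0.338), 0.0117 for 8q24 and 0.231 for 9p21 (0.0730). The 8q24 list lost its call with Spearman correlation, median scaling and the authors' values.

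Over the whole genome, genes next to each other on a chromosome correlated more than genes in shuffled order. The mean r of 12839 neighbouring pairs was 0.143, against at most 0.0142 in 1000 shuffles of the gene order (permutation p = 0.000999, the smallest possible, one-sided). Pairs 2 to 5 genes apart had a mean r of 0.106. With scan batch means removed the neighbours had 0.164. These are correlations averaged over gene pairs, and genes are not independent replicates.

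**Figure D3:**
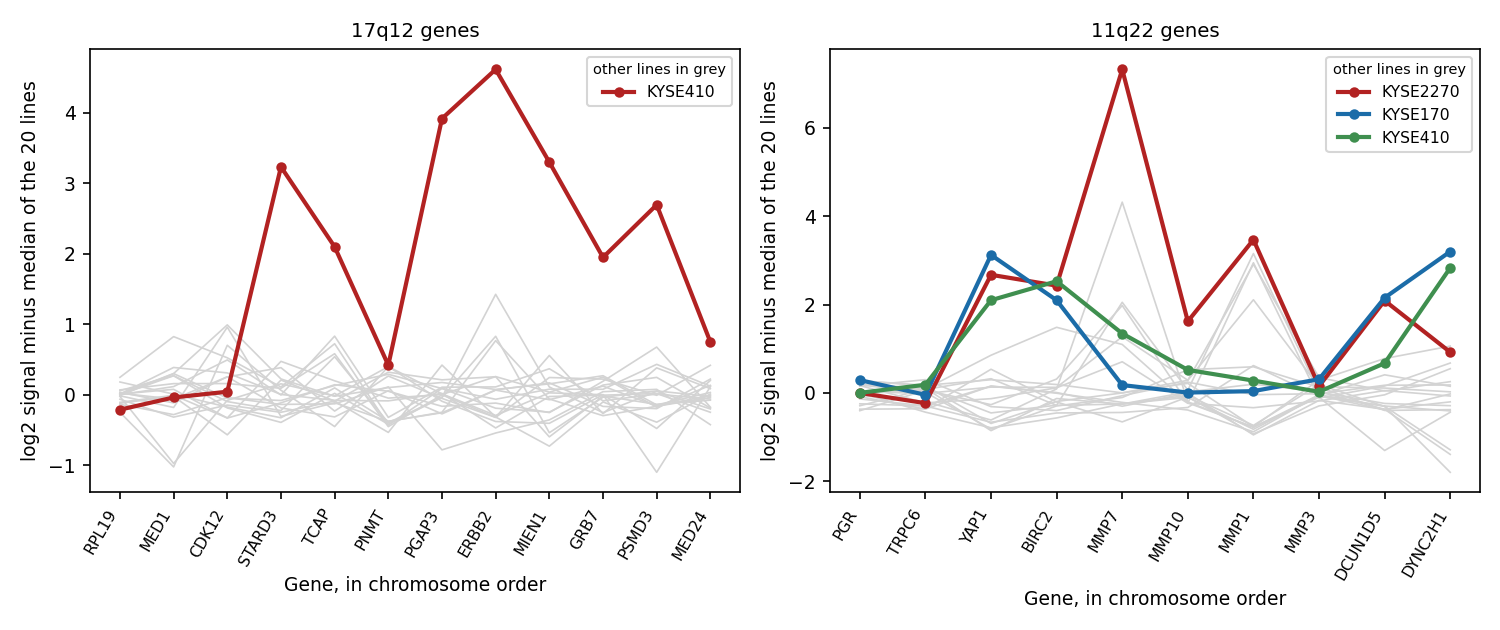
Log2 signal minus the median of the 20 lines for the genes of 17q12 and 11q22 in chromosome order, with 1 line of the plot per cell line. KYSE410 stands out in 17q12, with ERBB2 at 4.61, and KYSE2270 in 11q22, with MMP7 at 7.33.

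The median levels of the markers of other cell types were 7.57 for fibroblast, 6.79 for leukocyte, 6.72 for endothelial, 8.59 for columnar and gland and 7.37 for neuroendocrine genes. Single members lay higher, among them SYP (12.06), CD79A (10.11), TFF2 (10.11), PECAM1 (9.72) and LCP1 (9.67). Among 9 fibroblast genes, COL3A1, a fibrillar collagen, had 6.57 ± 1.30 and LUM 7.77 ± 1.11 (n = 19), and the high LUM value came from KYSE410 alone (mean r 0.0605, adjusted p = 0.231). The 12 leukocyte genes, with LAPTM5 (6.34 ± 1.12) and the T cell receptor chain CD3E (7.56 ± 0.53), had 0.0350 (adjusted p = 0.256). LAPTM5 also stood out in KYSE410, at 10.92 against 7.05 in the next line. So did TFF1 of the columnar and gland genes, at 10.21 against 7.20. The 7 endothelial genes, with the adhesion proteins ESAM (7.83 ± 0.70) and CDH5 (6.25 ± 0.53), had 0.172 (adjusted p = 0.0554, and 0.0266 with scan batch means removed). The 13 columnar and gland genes, with the secretory protein AGR2 (10.96 ± 2.11), KRT7 (8.59 ± 1.04) and TFF3 (8.84 ± 1.07, n = 19), had 0.0372 (adjusted p = 0.249). The 8 neuroendocrine genes, with the decarboxylase DDC (7.21 ± 1.09) and the adhesion protein NCAM1 (7.15 ± 0.61), had 0.0720 (adjusted p = 0.210). Of the erythroid and hepatocyte genes FGB (8.26 ± 0.23) and HBA1 (8.84 ± 0.19) passed detection, too few for a test.

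One label field of the KYSE890 sample names KYSE30, while its title names KYSE890. Once each gene's mean over the lines was removed, the arrays of KYSE890 and KYSE30 correlated across genes with r of -0.143, rank 131 of 190 pairs of arrays. The highest pair had 0.352, and pairs from the same scan batch had a mean of 0.111, against -0.124 for pairs from different batches. Some named genes differed between them too, with HMOX1 and UPP1 at their highest in KYSE30, and DPYD, CDA and NQO1 at their highest in KYSE890. KRT5 was near the floor in both, at 5.95 in KYSE30 and 6.22 in KYSE890.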

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

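All tests in this part were chosen after the data were seen.

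The arrays carry spots for bacterial genes as controls, which the comparisons above do not use. In scan batch 2 the spots of the bacterial gene LEUC had a median net intensity of 22.7 (21.8 to 33.0 on 8 arrays), where the 95th percentile of blank spots was at most 6.61, and the other 12 arrays lay between 4.38 and 10.2. The spots of YJEK, another bacterial gene, had a median of 21.3 in scan batch 2 (17.8 to 31.9 on 8 arrays), against 4.26 to 11.9 on the other 12 arrays. Every array of that batch lay at more than 2 times that limit for both genes. Other control genes also differed by batch: FIXA had medians of 18.4, 6.01 and 29.3 in batches 1, 2 and 3, and HISC had 95.6, 48.6 and 179. These intensities are not scaled for the brightness of the arrays. The median net signal of human probe spots was 358 to 443 on the arrays of batch 3 and 161 to 268 on the others. The higher values of batch 3 cannot be told apart from brightness.

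For 49 probes, among them those of HSPA8, EIF4G1 and PCNA, every array of at least 1 scan batch lay more than 2 on the log2 scale away from every array of the others. For the genes with another probe, HSPA8 among them, a difference of the lines in the gene itself is argued against. Their 19 other probes had a median gap between the same batches of 0.0321, where the split probes had 4.52. For the genes without another probe, EIF4G1 and PCNA among them, with 35 split probes in all, a difference in the gene itself cannot be told apart from array batch. All 49 of these probes were missing in the authors' table on the low batches, which is consistent with probes that could not be read on the arrays of that batch. That reading was made on the data that showed it, and the cause of the unreadable spots was not tested. In the table of the authors, the entries missing on every array of batch 1, 2 or 3, but not on all arrays, numbered 43, 91 and 196.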

How the results depend on the processing

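Removing scan batch means, the filter on negative control probes, the masking of values missing in the authors' table, the keeping of poor spots and the use of measured values only were chosen after the data were seen. The others were set before. Under the other settings 135 values of the planned results stayed within the limits set for no change and 30 moved. The number of co-expressed lists stayed between 16 and 21, the number of drug gene relations between 3 and 9, and the mean r of neighbouring genes between 0.135 and 0.164. Genes called for the NRF2 score ranged from 25 to 65. Of the values of single relations 678 kept their side of the threshold, 26 passed where the main value had not, and 4 no longer passed. Of the SDs of single genes 236 stayed and 40 moved. Of the slopes of single genes in the anchored fits 135 kept their call, 13 lost it and 1 turned its sign. The causes of the changes below were not tested, except that the filter for all 20 arrays leaves fewer genes. No paired analysis was possible because the lines form 1 group with 1 array each. The median signal of an array was at most 4.52 times its median background. This limits what can be read near the floor, and the gaps to lines at the floor are lower bounds.

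The variable genes, those with an SD above 1, numbered 1619 with the authors' values, where 79 genes stood out in a single line, and 333 with the filter for all 20 arrays, where 11 stood out. Single-line genes numbered 88 with a gap of at least 2, 18 with no background correction, 13 with scan batch means removed and 55 with poor spots kept. Relations between scores passed 5 times with scores from a principal component, 1 time with median scaling and 2 times with the filter for all 20 arrays, which left 3 drug gene relations. The cholesterol list also passed with the first principal component removed, Spearman correlation, no background correction, the mean of all probes and without KYSE890. The mesenchymal list passed with the mean of all probes, and the reductive activation list with Spearman correlation and with poor spots kept. The endothelial list passed without KYSE890, with the filter on negative control probes and with poor spots kept. The ribosomal list passed with median scaling and the authors' values, and with the filter for all 20 arrays the fibroblast list passed and the cancer-testis list did not. The arrays of KYSE890 and KYSE30 had r of 0.00932 with scan batch means removed.

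The NRF2 score called 25 genes with the filter for all 20 arrays. SRSF9 turned to a slope of 0.0351 with the authors' values. The proliferation score called 831 genes with the authors' values (384 up, 447 down) and 476 with median scaling (254 up, 222 down), against 1 in the main analysis. It called 14 with scan batch as a block (7 up, 7 down), 12 with the filter for all 20 arrays, 5 with the mean of all probes, 3 with measured values only, 4 with poor spots kept, 4 with values missing in the authors' table masked and 4 without KYSE890. The cornified score called 1 gene with no background correction, 1 with the authors' values and 1 without KYSE890. The interferon score called 1 gene with the mean of all probes, 1 with no filter and 1 with no background correction, and the mesenchymal score 1 with the covariate for the share of probes above background.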

Other observations

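The tests of the chromosome arm around TYMS and of the aldo-keto reductase paralogs were written before their results were seen. The other tests in this part, with the scan of chromosome windows, were chosen after the result was seen.

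Other stretches of chromosome stood out in single lines. A scan took the median of 11 neighbouring genes on values with scan batch means removed, unlike the region means given before. Set against the most extreme windows of 200 shuffled gene orders (1.16 and -1.03), it found 16 higher regions in 9 lines and 2 lower ones. The ends named are those of the region. Each value is that of its most extreme window of 11 genes, unless stated. The highest windows were around MMP7 and BIRC2 in KYSE2270 (2.49) and around ERBB2 in KYSE410 (2.09). KYSE410 had another region on the same chromosome, from FOXN1 to TAOK1, with the signal adaptor TRAF4. Its window from ALDOC to DHRS13 had 1.91, and the median over its 20 genes was 1.19. KYSE140 had higher windows around SOX2 (1.24) and from CARTPT to ENC1 (1.43), and KYSE150 had one from NEK2 to CENPF, a pair of mitotic genes (1.31). KYSE2270 had windows from MAN2A1 to MCC, with the tumour suppressor APC (1.21), and from BZW2 to MACC1 (1.18), with the secretory proteins AGR2 and AGR3. KYSE510 had a pair of windows on chromosome 18, from TYMS to TGIF1 (1.17) and from MAPRE2 to KIAA1328 (1.21). KYSE520, with the highest 18p11 mean before batch means were removed, had no window beyond the limit. KYSE220 had a region from CD22 to ZBTB32, with 1.29 in its window from CD22 to COX6B1 and a median of 0.15 over its 14 genes. KYSE850 had one on chromosome X from CNKSR2 to POLA1 (1.18).

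Clusters of like genes made up much of 5 higher regions. One was the highest region, around MMP7 and BIRC2, where 11 of 21 genes shared the first 3 letters of their names with another gene of the region. These 11 can belong to more than 1 family. Some protocadherins, adhesion proteins mostly known from neurons, were higher in KYSE180. The window from PCDHA7 to PCDHB10 had 1.68, and the median over the 16 genes of that region was 0.45. The small proline-rich and S100 genes of squamous differentiation, which lie side by side on chromosome 1, were higher in KYSE1250 (1.44), KYSE850 (1.42) and KYSE220 (1.24). The lower regions ran from FRYL to KIT in KYSE30 and from MMRN2 to CH25H in KYSE850, where the genes for the death receptor FAS and for glutamate dehydrogenase, GLUD1, lie. Their lowest windows had -1.09 (FRYL to LNX1) and -1.05 (MMRN2 to FAS), and the medians over the whole regions were -0.35 and -0.76.

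The NRF2 targets varied together over the lines. Scan batch is argued against as the whole cause, because their mean r was 0.449 with batch means removed, where the 95th percentile of random sets was 0.0398. Shared signal between the probes of the aldo-keto reductases, which resemble each other in sequence, is argued against as the whole cause by a mean r of 0.420 for the 20 targets without them, with a bound of 0.0438. A candidate explanation is that the activity of NRF2 differs between the lines, which stays an untested hypothesis, since the data hold no measure of NRF2 protein or mutation.

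TYMS followed its 18p11 neighbours over the lines. In these tests its poor spot in KYSE590 was set to the gene's mean. Scan batch is argued against by an r of 0.858 with batch means removed (permutation within batches, p = 2e-05). TYMS did not follow the proliferation score (r -0.082, upper 95% bound 0.3741), though r was 0.537 within batch 2. The growth rate of the cultures was not measured, and the neighbours of TYMS were not set against that score. This test therefore cannot decide on growth rate. If the dosage of the short chromosome arm differs between the lines, TYMS should follow other genes of that arm too. The mean r of TYMS with 39 short-arm genes outside the list was 0.1415 (bound of random sets 0.0965, p = 0.0028 against random sets, smallest possible p 0.0001). With 143 genes of the long arm it was 0.0085. The 39 genes were not limited by distance and hold TGIF1 and MYL12B, which lie in the window that starts at TYMS in KYSE510. An effect local to TYMS could give the same result, so the test cannot tell it from dosage of the whole arm. DNA copy number was not measured, and regulation shared by neighbouring genes stays open.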
